A study of Mus musculus with 6 samples.

How the data were processed

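The data are bulk RNA-sequencing libraries from ligated mouse kidneys, 3 from wild-type and 3 from Mir92b knockout mice. Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with an mRNA kit, and kidneys were collected 10 days after the operation. The authors deposited whole-number read counts per gene symbol, 1 column per library, without normalization. GRCm38 and mm10, which are names of the same build, are listed in the submitters' processing notes. The aligner, the counting program and whether counting used strand are not given in the sources used here. Overlapping, antisense and near-identical genes may therefore share counts.

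The table holds 34714 rows, of which 8308 are 0 in every library. All symbols were found in the RefSeq gene table of assembly GRCm38.p6, which gave the coordinates. The table has 0 microRNA rows and 0 mitochondrially encoded rows. The wild-type columns carry the name given in the library's description. The knockout columns give the parts of that name in another order, and each was matched by those parts and its number. Groups and replicate numbers came from the titles.

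Genes were filtered with filterByExpr, which kept 18927 genes with 99.96% of all counts. Counts were scaled by TMM, and the groups were compared with the quasi-likelihood F test of edgeR 4.0.16 (estimateDisp, glmQLFit with robust = TRUE) in R 4.3.3, with group as the only term. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The biological coefficient of variation was 26.9%. Log2 CPM used a prior count of 2. Standard errors are the log2 fold change divided by the root of the F statistic. For Tgfbr1 the exact permutation test of log2 CPM was added, whose smallest two-sided p is 0.1.

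Gene lists covered TGF-β and related pathways, matrix, kidney, immune and vascular cell types, metabolism, stress, other tissues, RNA handling, the Mir92b locus and named targets of the miR-92 family. Lists, tests and alternatives were fixed before the data were examined, unless stated otherwise. The 46 lists with at least 3 measured genes were tested with camera from limma 3.58.1 on log2 CPM, with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Lists of pancreas and mitochondrially encoded genes had too few measured genes. No call held with an estimated correlation, where the smallest adjusted p was 0.0873. With fry, 1 list was called. For 5 lists, none of them called, the median fold change and the direction of the test differed in sign.

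Genes were named by a fixed rule. It took a list of TGF-β, matrix, injury and fibrosis genes always, and genes past the adjusted threshold with non-overlapping groups and a mean of at least 5 CPM in one group. Predicted genes (symbols that begin with Gm and a digit, or end in Rik) were left out. Where fewer than 5 passed in a direction, it took the 5 with the smallest p, named as not passing. From each list it took up to 3 members with the smallest p and a mean of at least 1 CPM. Egr1, and in the closing section the genes outside this rule, were chosen after their values were seen. One gene that the rule names is not reported here.

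Seed sites were searched in the longest annotated 3' UTR per gene, built from GENCODE M21 transcripts and coding ends, for the 8mer GTGCAATA, its first 7 bases (7mer-m8) and its last 7 bases (7mer-A1). Of the tested genes, 15384 had a 3' UTR to search. Transcript length was the longest GENCODE M21 transcript of a symbol and was found for 89.7% of the tested genes. The length trend was removed by fitting a loess curve of each library's log2 CPM deviation on log10 length and passing it to edgeR as an offset.

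The pipeline was tested on simulated counts for 18619 genes with the means and library sizes of this comparison. The genes to be changed were drawn from those with a mean of at least 1 CPM, so recovery among weaker genes was not measured. The pipeline recovered 3 of 67 genes changed 1.5-fold (4.48%), 27 of 67 changed 2-fold (40.3%) and 55 of 66 changed 4-fold (83.3%). Beside these there were 10 calls among unchanged genes. A list shifted by 0.5 on the log2 scale was recovered by camera at an adjusted p of 0.000719, with 0 other lists called. The simulated genes were drawn independently of one another. In the real lists the estimated inter-gene correlation reached 0.92, so the simulation does not measure how often camera calls lists falsely in these data.

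Alternatives were DESeq2 size factors, upper-quartile factors and library size alone, the Wald test of DESeq2 1.42.0, limma-voom with quality weights, no filter, a filter of 1 CPM in 3 libraries, robust fitting off, a threshold of 0.01, a test against a fold of 1.5, the replicate number as a block, and each library left out in turn. For pairs of libraries, the chi-square of counts per degree of freedom was 33.6 or more, so no library was a copy of another. A few genes did not dominate: the 10 most abundant genes took 4.69% to 6.85% of the counts.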

Results

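Gene expression was measured by RNA sequencing in kidneys of mice 10 days after unilateral ureteral obstruction, an operation in which the ureter of one kidney is tied off and the kidney scars. Per the labels, the mice were male, 8 weeks old and on a C57BL/6 background. The 6 libraries fall into 2 groups, 3 from wild-type mice and 3 from mice with a global deletion of the microRNA gene Mir92b. The kidneys were taken to be obstructed from the treatment label and the names of the count columns, although the treatment protocol describes ligated kidneys as controls without fibrosis. The tubule injury markers Havcr1 and Lcn2 were expressed in all 6 libraries, at 443 to 1387 CPM and 298 to 562 CPM, but no unobstructed kidney was analysed for comparison. Unoperated or sham-operated kidneys were not analysed here. The library totals were 38738204, 47893534 and 51932509 counts in the wild type and 44476507, 46804547 and 50769801 counts in the knockout. The labels do not say that the replicates are separate animals, and if they are not, the p-values measure a technical spread only.

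Mir92b, the deleted gene, lies on chromosome 3 at 89227116 to 89227198 (GRCm38), between the protein-coding genes Thbs3, which ends at 89226841, and Muc1, which starts at 89229056. The table of counts analysed here holds no row for a microRNA, so the deletion could not be checked against the labels. The 12 measured genes around the locus had a median log2 fold change (knockout over wild type) of -0.09 and did not differ from other genes (camera adjusted p = 0.475). The strongest of them by p was Dpm3, at -0.41 ± 0.21 (SE, n = 3 per group; edgeR adjusted p over all genes above the threshold of 0.05), and at -0.16 with the transcript length trend removed.

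The comparison asks what loss of the microRNA does to the obstructed kidney. The gene with the smallest p was Jchain, the joining chain of polymeric antibodies, at 5.19 ± 1.58 CPM (normalised counts scaled to library size; SD, n = 3) in the wild type and 83.2 ± 27.7 CPM in the knockout, a 16.0-fold difference. Its log2 fold change was 4.003 ± 0.34 (SE), higher in 3 of 3 knockout libraries, with an edgeR quasi-likelihood adjusted p of 0.0568 that ranged from 4.82e-31 to 0.735 over the alternatives. It passed without knockout replicate 3 (edgeR adjusted p = 0.0169), with no filter (0.0307) and with the replicate block (0.0221), and also with limma-voom (0.0158). Other genes were ranked by p among those with a mean of at least 5 CPM in a group and groups that did not overlap. Symbols of predicted genes were left out. The next 4 on the higher side were Castor2, a regulator of the mTORC1 pathway (log2 fold change 1.05), Fzd1, a Wnt receptor (0.85), Fbn2, a microfibril protein (1.24), and Sorcs1 (0.86). The 5 with the smallest p on the lower side were Ccn1, a matricellular protein (-1.65), Hdc, the enzyme that makes histamine (-1.37), Fxyd4, a collecting duct regulator of the sodium pump (-0.76), Ifit1, an interferon-induced gene (-0.69), and Fos, an immediate early transcription factor (-3.47). With all libraries and the main settings, none of these 10 genes passed the adjusted threshold with edgeR. All 10 passed with the DESeq2 Wald test, at adjusted p from 4.82e-31 for Jchain to 0.0453 for Ifit1. The muscle genes Myh4 and Myh1, which lie under 5 CPM, had a smaller p than the other genes on the lower side (edgeR adjusted p = 0.233 and 0.438).

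Of 18927 genes tested, 0 were higher and 0 were lower in the knockout at an adjusted p under 0.05 (edgeR). At an unadjusted p under 0.05 there were 829 higher and 666 lower genes, 1495 in all, where 946 would be expected with no effect. DESeq2 called 29 genes higher and 24 lower, and limma-voom called 1 higher and 2 lower. The groups did not overlap for 16.1% of the genes, against 10% by chance.

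Tgfbr1, the type I receptor of TGF-β that the series title names as the target, was expressed at 167 ± 10.3 CPM (SD, n = 3) in the wild type and 217 ± 7.78 CPM in the knockout. All 3 knockout libraries (208, 223 and 219 CPM) lay above all 3 wild-type libraries (167, 177 and 156 CPM), a 1.30-fold difference. The log2 fold change was 0.38 ± 0.13 (SE), with an edgeR adjusted p of 0.627 over all genes tested and 0.198 when adjusted over the list alone. The exact two-sided permutation test of its log2 CPM gave p = 0.1, the smallest that 3 against 3 allows. Tgfbr2, the type II receptor, differed by 0.51 ± 0.19 on the log2 scale, also without overlap (edgeR adjusted p = 0.627). Tgfb1, the ligand, was at 0.28 ± 0.17, and the signal transducers Smad2, Smad3 and Smad4 at 0.30, 0.24 and 0.29. The inhibitor Smad7 was at -0.04 ± 0.12. Single libraries weighed on these values: Smad2 and Smad4 were at 0.11 and 0.18 without wild-type replicate 1, Tgfb1 and Smad3 at 0.14 and 0.16 without knockout replicate 3, and Tgfb1 at 0.43 without knockout replicate 1. With replicate 3 of both groups left out, an alternative chosen after the data were seen, Tgfb1 and Smad3 were at 0.17 and 0.10.

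The list of TGF-β ligands, receptors and SMADs also held SMAD regulators, latent TGF-β binding proteins, integrins, Lrrc32 and Thbs1. As a group, its 27 measured genes were shifted upward against other genes, with a median log2 fold change of 0.29 (camera adjusted p = 9.1e-06). The call was lost at adjusted p = 0.856 with an estimated correlation. The fold change was above 0 for 24 of the 27, and the mean of the list was higher in every knockout library than in every wild-type library. No member passed over all genes with edgeR. When adjusted over the list alone 1 passed, Ltbp2, a member of the latent TGF-β binding protein family, at 0.77 ± 0.15. DESeq2 also called Ltbp2 over all genes (adjusted p = 0.0294). Thbs1, an activator of latent TGF-β, stood at 0.61 ± 0.16. Neither Ltbp2 nor Thbs1 is a ligand, receptor or SMAD, and both also stand in the list of TGF-β response genes. Long transcripts tended to be higher in the knockout (given with the other RNA measures), and with that trend removed the median of the list was 0.18 (adjusted p = 0.000905) and Tgfbr1, Tgfbr2, Smad2 and Smad3 stood at 0.26, 0.33, 0.13 and 0.13.

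**Figure D1:**
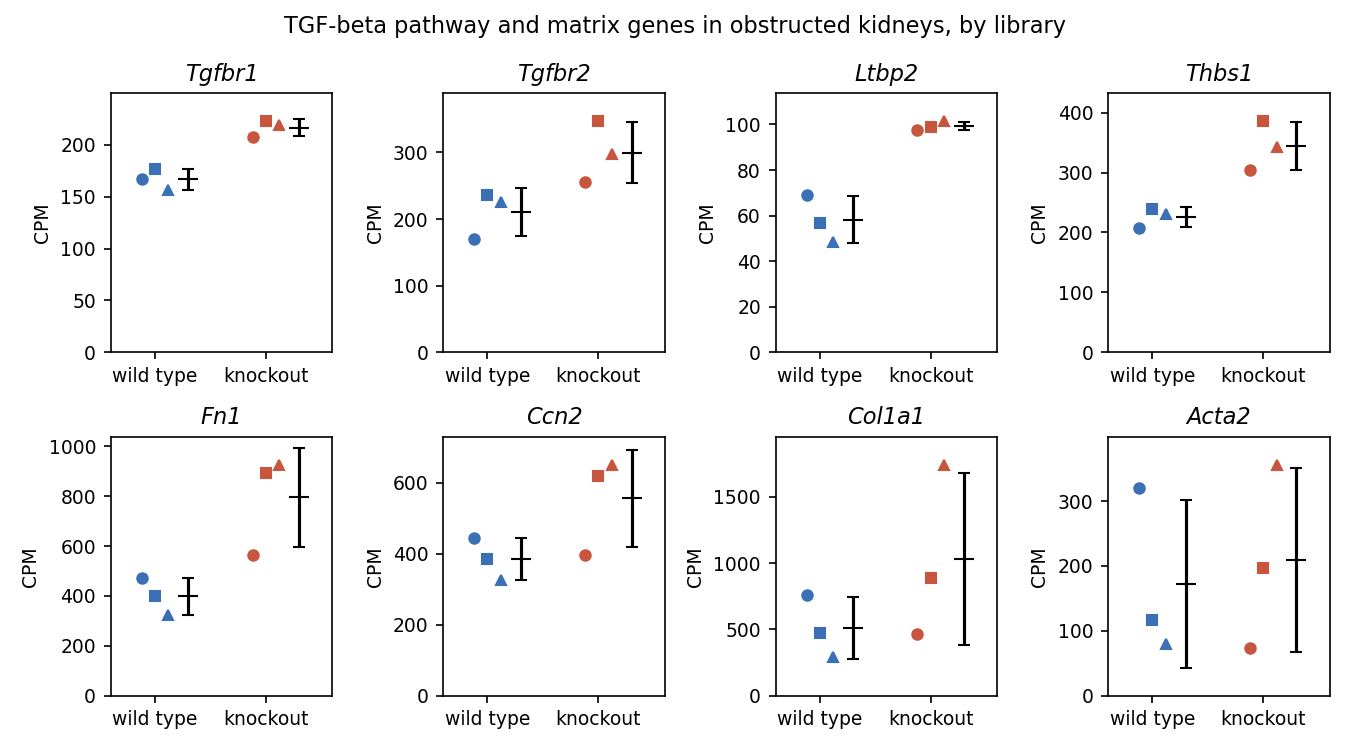
Normalised counts (CPM, vertical axes from 0) of 8 genes in the 3 wild-type (blue) and 3 knockout (red) libraries, with replicates 1, 2 and 3 as circles, squares and triangles and the mean ± SD in black. Tgfbr1, Tgfbr2, Ltbp2, Thbs1 and Fn1 do not overlap between groups, whereas Col1a1 and Acta2 spread widely within each group.

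A microRNA of the miR-92 family pairs through its seed with the sequence GTGCAATA (an 8mer site) in the 3' UTR of its targets, and family members such as miR-25, miR-32 and miR-92a share that seed. The longest annotated 3' UTR of Tgfbr1 (chromosome 4, gene at 47353222 to 47414926, plus strand; 4154 nt) held 0 sites of the 8mer, 7mer-m8 and 7mer-A1 types and 1 6mer (TGCAAT) at 3' UTR position 3755, which is 47414532 to 47414537. A 7mer-A1 site (TGCAATA) lay in the coding sequence at 47383967 to 47383973. The sites searched are those of miR-92b-3p. Sites for any other product of Mir92b were not searched, here or across the transcriptome. Across the transcriptome, the 415 tested genes with an 8mer in the longest 3' UTR had a median log2 fold change of 0.07, and the 13250 genes with none of the 3 site types a median of 0.00336. The difference of 0.0701 gave a camera p of 0.0311, but it lay at percentile 33.8 of the differences for 1679 control 8mers made of the same bases in another order, whose median was 0.0809. Against genes matched on 3' UTR length and expression the difference was -0.0239. The camera p lay above 0.05 without wild-type replicate 1 (difference 0.0294), wild-type replicate 3 (0.0843), knockout replicate 1 (0.0773) or knockout replicate 2 (0.0317). The 28 measured genes from a list of named miR-92 family targets had a median of 0.01 (camera adjusted p = 0.571), with Bcl2l11, a pro-apoptotic gene, at 0.49 ± 0.15 (0.31 with replicate 3 of both groups left out).

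Genes of the extracellular matrix tended to be higher in the knockout. Of 32 ECM glycoproteins and proteoglycans, 31 had a fold change above 0, with a median log2 fold change of 0.59 (camera adjusted p = 1.21e-09; adjusted p = 0.891 with an estimated correlation). Of 22 collagens, 19 were above 0, with a median of 0.73 (camera adjusted p = 3.29e-07; adjusted p = 0.856 with an estimated correlation). Fn1, fibronectin, measured 398 ± 74.1 CPM (SD, n = 3) in the wild type and 795 ± 200.3 CPM in the knockout, a log2 fold change of 1.00 ± 0.25. Fbn1 (fibrillin) and Prelp differed by 1.19 ± 0.26 and 1.22 ± 0.29, and the collagens Col12a1, Col15a1 and Col4a2 by 1.35 ± 0.25, 1.04 ± 0.25 and 0.72 ± 0.21. No member passed over all genes with edgeR, and 4 glycoproteins and 2 collagens passed when adjusted over the list alone. DESeq2 called Fn1, Fbn1, Prelp, Col12a1 and Col15a1 over all genes (adjusted p = 0.0402, 0.0170, 0.0453, 0.00118 and 0.0409). The classical fibrosis collagens varied more between libraries, with Col1a1 at 1.03 ± 0.51, Col1a2 at 0.74 ± 0.41 and Col3a1 at 0.85 ± 0.43; they were at 0.42, 0.29 and 0.50 without knockout replicate 3, and at 0.15, 0.094 and 0.27 with replicate 3 of both groups left out. The per-library means of both lists overlapped between the groups, and without knockout replicate 3 the glycoprotein median was 0.32. With replicate 3 of both groups left out the medians were 0.17 for glycoproteins and 0.37 for collagens (camera adjusted p = 0.0435 and 0.00831). With the length trend removed the medians were 0.53 for glycoproteins and 0.62 for collagens, both still called.

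Other groups tied to fibrosis had smaller medians, and their calls were lost when single libraries were left out. The 28 genes of matrix crosslinking and turnover had a median of 0.35 (camera adjusted p = 0.00129; adjusted p = 0.907 with an estimated correlation), led by the protease inhibitor Timp2 at 0.76 ± 0.22, the gelatinase Mmp2 at 0.93 ± 0.28 and the crosslinking enzyme Loxl2 at 0.83 ± 0.29. The 27 TGF-β response genes had a median of 0.39 (camera adjusted p = 0.00181, and 0.958 with an estimated correlation). Of the 4 that passed when adjusted over the list alone, Ltbp2, Fn1 and Thbs1 were higher and Ccn1 was lower. The response list shares genes with the matrix lists and with the list of TGF-β ligands, receptors and SMADs, so its call is not separate from theirs. The 24 markers of myofibroblasts and fibroblasts had a median of 0.42 (camera adjusted p = 0.00113; adjusted p = 0.994 with an estimated correlation), with Dpt at 0.88 ± 0.28, Pdgfra at 0.77 ± 0.28 and Cspg4 at 0.36 ± 0.15. The myofibroblast gene Acta2 was at 0.28 ± 0.66, Vim at 0.24 ± 0.50 and Ccn2 at 0.53 ± 0.23. With replicate 3 of both groups left out Loxl2, Dpt and Ccn2 were at 0.46, 0.54 and 0.30, and with the length trend removed Cspg4 was at 0.18. Without knockout replicate 3, the medians of these 3 lists were 0.08, 0.13 and 0.03 and none was called (camera adjusted p = 0.0676, 0.164 and 0.23), and Acta2 and Vim turned to -0.35 and -0.41. With replicate 3 of both groups left out the medians were 0.091, 0.090 and -0.22, again with no call (camera adjusted p = 0.306, 0.542 and 0.606). The fibroblast list also lost its call without wild-type replicate 3, at a median of 0.35 (camera adjusted p = 0.157); without wild-type replicate 1 or knockout replicate 1 its median was 0.77 or 0.71, and that of the response genes 0.64 or 0.69.

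The 24 measured Wnt pathway genes had a median of 0.31, with 20 above 0 (camera adjusted p = 0.000367; adjusted p = 0.856 with an estimated correlation). Fzd1, the secreted Wnt modulator Sfrp1 and the coreceptor Lrp5 passed when adjusted over the list alone, at 0.85 ± 0.14, 1.06 ± 0.23 and 0.75 ± 0.19. With replicate 3 of both groups left out Sfrp1 was at 0.70. Without wild-type replicate 3 the list median was 0.20 and the call was lost (camera adjusted p = 0.0919), and with the stricter filter (1 CPM in 3 libraries) the median was 0.20 and the call held (0.00141).

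**Figure D2:**
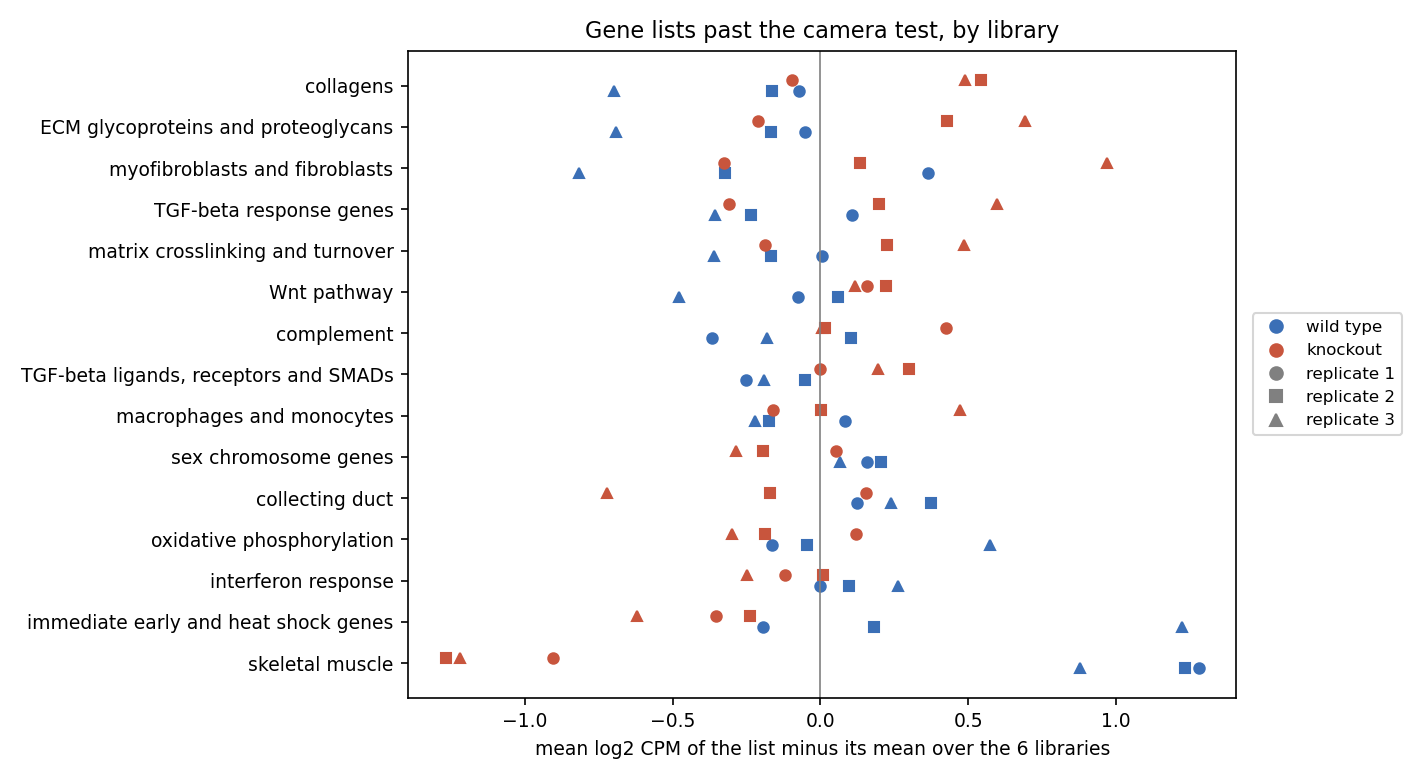
Mean log2 CPM of each of the 15 lists called by camera, minus its mean over the 6 libraries (horizontal axis), for wild-type (blue) and knockout (red) libraries, with replicates 1, 2 and 3 as circles, squares and triangles. The groups part for skeletal muscle, the TGF-β pathway, the immediate early genes, the Wnt pathway and the sex chromosome genes, and overlap for the other 10 lists.

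Among the epithelial groups, collecting duct markers shifted downward, with a median log2 fold change of -0.25 and 15 of 16 below 0 (camera adjusted p = 0.00129; adjusted p = 0.907 with an estimated correlation). Fxyd4 passed when adjusted over the list alone, at -0.76 ± 0.15, and the transcription factor Elf5 and the water channel Aqp4 were at -1.49 ± 0.42 and -1.17 ± 0.42. Without knockout replicate 1 the median was -0.41 and without knockout replicate 3 it was -0.13, both still called; with replicate 3 of both groups left out it was -0.16 (camera adjusted p = 0.0435). The 26 oxidative phosphorylation genes had a median of -0.29, with 22 below 0 (camera adjusted p = 0.00163; adjusted p = 0.994 with an estimated correlation), led by the small subunits Ndufa1, Cox5b and Cox7b at -0.64, -0.62 and -0.64. That call was lost without wild-type replicate 3, at a median of -0.02 (camera adjusted p = 0.821), and without knockout replicate 3, at -0.22 (0.0641), and the median was -0.44 without knockout replicate 1 and 0.059 with replicate 3 of both groups left out (0.518), where Ndufa1 and Cox7b were at -0.39 and -0.38. With limma-voom the 3 genes were at -0.34, -0.40 and -0.38. With the length trend removed the list median was -0.18 (camera adjusted p = 0.0448), with Ndufa1 at -0.33 and Cox5b at -0.39. Proximal tubule markers had a median of -0.32 and were not called (camera adjusted p = 0.224). The median turned to 0.31 without wild-type replicate 3 and to 0.02 without knockout replicate 3, and the list was called lower without wild-type replicate 1 (-0.54) or knockout replicate 1 (-0.76). With replicate 3 of both groups left out it was called higher, at a median of 0.55 (camera adjusted p = 1.18e-05). These calls used the preset correlation, and with all libraries the list had an adjusted p = 0.994 with an estimated correlation. The injury markers Havcr1 and Lcn2 were at 0.16 ± 0.37 and -0.15 ± 0.26, Cdh1, the epithelial cadherin, at 0.16 ± 0.22, and the injured tubule list at a median of 0.07 (camera adjusted p = 0.81).

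Interferon response genes shifted downward in the knockout, with 19 of 24 below 0 and a median of -0.29 (camera adjusted p = 0.000161; adjusted p = 0.479 with an estimated correlation). Ifit1, Isg15 and Ifit3 were at -0.69 ± 0.14, -0.86 ± 0.19 and -0.52 ± 0.12, and 6 genes of the list passed when adjusted over the list alone. The median was -0.14 without wild-type replicate 3, still called, and -0.14 with replicate 3 of both groups left out, where the call was lost (camera adjusted p = 0.127). Complement genes shifted upward, with 17 of 18 above 0 and a median of 0.29 (camera adjusted p = 0.0043; adjusted p = 0.479 with an estimated correlation); C1qb was at 0.33 ± 0.13 (0.52 with the length trend removed) and C1s1 at 0.39 ± 0.18 (0.25 without knockout replicate 2), whereas Cd55, which restrains complement, was at -0.31 ± 0.15. The 24 macrophage and monocyte markers had a median of 0.19 (camera adjusted p = 0.0317; adjusted p = 0.907 with an estimated correlation), with Itgam at 0.40 ± 0.13, Lyz2 at 0.55 ± 0.19 and Lgals3 at -0.55 ± 0.20. That call was lost without wild-type replicate 2 (median 0.17), wild-type replicate 3 (0.17), knockout replicate 3 (0.03) or replicate 3 of both groups (0.057), with the stricter filter (0.16) and among genes with an annotated length (0.19).

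Gene lists that report on tissue handling or on other tissue, and the list of sex chromosome genes, also differed between the wild-type and knockout libraries. Immediate early and heat shock genes were lower in the knockout, with a median of -0.86 and 17 of 22 below 0 (camera adjusted p = 0.000156; adjusted p = 0.994 with an estimated correlation). Fos measured 63.5, 84.4 and 377 CPM in the wild-type libraries and 17.9, 16.1 and 13.3 CPM in the knockout libraries; Dusp1, Zfp36 and Egr1 were at -1.52 ± 0.37, -1.46 ± 0.37 and -1.94 ± 0.50, and 10 genes passed when adjusted over the list alone. Without wild-type replicate 3, which held the highest levels, the median was -0.35 and the list was still called, but with replicate 3 of both groups left out it was -0.19 and the call was lost (camera adjusted p = 0.0723). Fos, Dusp1, Zfp36 and Egr1 were at -2.23, -0.90, -0.86 and -1.18 without wild-type replicate 3. Skeletal muscle genes were low throughout but lower in the knockout, with 12 of 12 below 0 and a median of -2.78 (camera adjusted p = 5.15e-19; adjusted p = 0.0873 with an estimated correlation; fry adjusted p = 0.00127). Myh4, a fast myosin, measured 1.43, 1.07 and 1.11 CPM in the wild type and had 0 counts in all 3 knockout libraries, at least 18.8-fold lower against a floor of 3 counts per library; with such genes at their bound the list median was -2.72. The stricter filter kept 5 of the 12 genes, with a median of -0.93 (camera adjusted p = 1.33e-06). Acta1 was at -2.24 ± 0.38 and Tnni2 at -0.91 ± 0.35. The 5 measured sex chromosome genes had a median of -0.23 (camera adjusted p = 0.0302; adjusted p = 0.891 with an estimated correlation), with Eif2s3y at -0.45 ± 0.13. This call was lost without wild-type replicate 2 (median -0.24), wild-type replicate 3 (-0.21), knockout replicate 3 (-0.15) or replicate 3 of both groups (-0.13).

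Fold changes also followed transcript length. Among the 16975 tested genes with an annotated length, the rank correlation of length and log2 fold change was 0.347 across genes, which are not independent replicates, against 0.00702 for GC content. The slope of expression on length, in log2 units per 10-fold length, was -0.353, 0.0281 and -0.271 in the wild-type libraries and 0.0879, 0.335 and 0.173 in the knockout libraries.

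**Figure D3:**
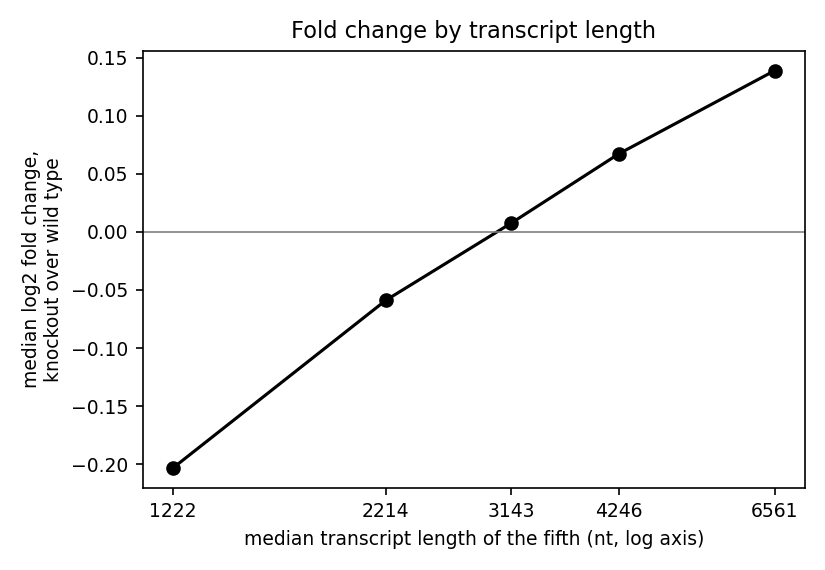
Median log2 fold change of knockout over wild type (vertical axis) in 5 equal groups of genes ordered by transcript length, plotted at the median length of each group (nt, log axis). The medians run from -0.20 for the group of shortest transcripts to 0.14 for that of the longest.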

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

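The alternatives that remove the length trend, keep only genes with an annotated length, or leave out wild-type replicate 3 together with knockout replicate 3 were chosen after the data were seen. Those 2 libraries are the ends of the first principal component, so leaving them out is not a neutral choice. The counts of 0 genes higher and 0 lower held under the other scalings, the stricter filter, robust fitting off, the stricter threshold and the fold test. DESeq2 called 29 higher and 24 lower, limma-voom 1 and 2, and no filter 1 and 1. Leaving out both libraries called 1 higher. Leaving out single libraries gave 0 to 1 higher and 0 lower. The cause was not tested. Same-numbered libraries did not deviate together (correlations of deviations from the group means -0.282, 0.179 and -0.288), and wild-type replicates 1 and 3 correlated best with knockout replicates 3 and 1. These values gave no sign that the numbers pair the samples. Deviations within a group depend on one another, so a shared litter, day or batch is not excluded. With the replicate number as a block, 1 gene was called higher, the Tgfbr1 log2 fold change was 0.38, 15 lists were called and the seed-site difference was 0.0727.

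Tgfbr1 stayed above 0 and short of the threshold in every alternative run, at 0.34 to 0.43 with single libraries left out. The number of lists called, 15, was 13 to 21 with single libraries left out, 0 with an estimated correlation, 1 with fry, 17 with the length trend removed and 19 with both libraries left out. The seed-site difference was 0.0294 to 0.116 with single libraries left out and -0.0239 against matched genes. The cause was not tested in these cases.

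Of the genes named, those near 0 changed sign under some alternatives. With both libraries left out, Smad7 was at 0.074, Acta2 at -0.69 and Vim at -0.59; limma-voom put Smad7 at 0.013, and with the length trend removed Lcn2 was at 0.014. With single libraries left out, the ranges were -0.082 to 0.026 for Smad7, -0.35 to 1.09 for Acta2, -0.41 to 0.77 for Vim, -0.031 to 0.30 for Cdh1, -0.17 to 0.59 for Havcr1 and -0.37 to 0.090 for Lcn2. With both libraries left out, the list medians were -0.22 for fibroblasts, 0.059 for oxidative phosphorylation, 0.55 for proximal tubule and -0.31 for endothelium, all reversed. The direction of the miR-92 target list turned with the length trend removed (median -0.063). With single libraries left out, the medians ranged from -0.038 to 0.073 for miR-92 targets, -0.76 to 0.31 for proximal tubule, -0.20 to 0.50 for endothelium and -0.22 to -0.021 for the Mir92b locus, each with a reversed test direction in at least 1 of those fits. The cause was not tested. The alternative without mitochondrially encoded genes was not run, since none was measured. The smallest library held 38738204 counts, and a count of 0 allowed up to 0.0596 to 0.0705 CPM depending on the library (3 counts, counting error only).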

Other observations

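The second lists of muscle and plasma cell genes, and the counts over other splits of the libraries, were planned before their results were seen; the tests of transcript length and of tubule share were chosen only afterwards, as were the split count for the length trend and leaving out replicate 3 of both groups.

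Inflammatory genes outside the called lists went both ways. Of 25 chemokines 15 were above 0, and at an unadjusted p under 0.05 there were 3 above and 5 below. Cxcl2 and Cxcl1, which attract neutrophils, were at -1.02 ± 0.28 and -1.12 ± 0.41 (SE, n = 3 per group), while Ccl19, Cxcl9 and Cx3cl1 were at 1.43 ± 0.55, 0.91 ± 0.36 and 0.52 ± 0.21. Among cytokine genes, Il1b was at -1.45 ± 0.54 and the receptor Tnfrsf1b at 0.64 ± 0.15. None of these passed the adjusted threshold with edgeR or DESeq2. Without wild-type replicate 3, Cxcl1 was at -0.55 and Il1b at -0.43, with replicate 3 of both groups left out Cxcl2 was at -0.57 and Cxcl9 at 1.40, and without knockout replicate 2 Ccl19, Cxcl9 and Cx3cl1 were at 0.79, 0.48 and 0.27. The chemokine list had a median of 0.13 and the inflammatory cytokine list one of -0.10 (camera adjusted p = 0.938 and 0.475). Gzmb, a granule protease, measured 5.05 CPM in the wild type and 1.25 CPM in the knockout (log2 fold change -2.02, and -0.75 without wild-type replicate 3), and the list of NK and cytotoxic cells had a median of -0.20 (camera adjusted p = 0.184). T cells, dendritic cells and neutrophils had medians of 0.10, 0.09 and -0.26, and B and plasma cells one of 0.19. Among the podocyte markers, the slit diaphragm gene Nphs1 was at -0.68 ± 0.20 (-0.45 without wild-type replicate 1) and Vegfa at -0.59 ± 0.21, but the list had a median of -0.03. Vegfa also stands in the list of glycolysis and hypoxia, and bulk libraries do not show which cells its value comes from. The urothelial keratins Krt7 and Krt15 were at -0.48 ± 0.14 and -1.16 ± 0.35 (Krt15 at -0.70 without wild-type replicate 2), in a list with a median of -0.14.

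The remaining lists were not called by camera with all libraries. Endothelium was called higher without wild-type replicate 1 (median 0.50, camera adjusted p = 0.0078) or knockout replicate 1 (0.43, 0.00212), and its median was -0.20 without knockout replicate 3; with all libraries its adjusted p = 0.994 with an estimated correlation. With all libraries the median log2 fold changes were 0.17 for endothelium, 0.27 for smooth muscle and pericytes, 0.24 for epithelial and mesenchymal state, -0.11 for thick ascending limb and distal tubule, -0.07 for the BMP pathway and 0.08 for proliferation. They were 0.02 for fatty acid oxidation, 0.05 for glycolysis and hypoxia, 0.04 for the unfolded protein response, -0.11 for oxidative stress, 0.03 for apoptosis and necroptosis, -0.07 for cholesterol synthesis and -0.14 for ribosomal proteins. For blood the median was 0.38, for liver -0.24, for adrenal gland -0.29, and for hosts of the miR-25/92 clusters 0.19. Adipose genes had a median of 1.68 but varied between libraries rather than groups. Their mean log2 CPM was 2.14, 4.03 and 1.55 in the wild type and 5.52, 1.20 and 2.32 in the knockout.

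There are 10 ways to split 6 libraries into 3 and 3, too few to reach a share under 0.05. For genes at an adjusted p under 0.05 the real split gave 0, and so did all 10. For genes at an unadjusted p under 0.05 the real split gave 1495 and the highest other split 1845, with 3 of 10 as high as the real one. For lists called, the real split gave 15 and the highest other split 26, with 8 of 10 as high. The seed-site difference was 0.0701 in the real split and 0.101 in the highest other, with 2 of 10 as large. The length correlation was 0.347 and 0.348, again with 2 of 10 as large.

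Jchain was 16.0-fold higher in the knockout, and a candidate explanation is a larger number of plasma cells, which predicts a median log2 fold change above 1 for a second list of plasma cell genes, of which 11 of 12 were measured and 1, Mzb1, also stands in the fixed list of B and plasma cells. The median was 0.11 (95% interval over resampled genes -0.08 to 0.39), and only 1 of the 11 genes had a wild-type level above the 78.0 CPM to be explained. That comparison assumes that plasma cells would add as much of each gene as of Jchain, which was not tested. The median therefore cannot decide on plasma cell number. Mzb1 stood at 3.34 CPM in the wild type and 3.94 CPM in the knockout, so it did not rise with Jchain to a like degree. A change in plasma cell number stays open. The highest of the second list were Pou2af1 at 1.43 ± 0.49, Tent5c at 0.80 ± 0.23 and Txndc5 at 0.39 ± 0.16, the last 2 without overlap. Pou2af1 was low, at 0.713 CPM in the wild type and 1.92 CPM in the knockout. Of the rest, Derl3, Mzb1, Irf4, Fkbp11 and Prdm1 were at 0.35, 0.24, 0.11, 0.05 and 0.02. Pim2, Tnfrsf13b and Eaf2 were at -0.08, -0.23 and -0.46. The fixed B and plasma cell list holds Jchain itself, so its calls are not separate evidence. It was called without knockout replicate 3 (median 0.25, camera adjusted p = 0.0113) and with replicate 3 of both groups left out (0.19, 0.0435). That list was not called with all libraries (median 0.19, camera adjusted p = 0.253, and 0.994 with an estimated correlation). Without knockout replicate 2 its median was -0.068 (camera adjusted p = 0.957). A change in Jchain within the cells that express it, a difference between the strains' Jchain loci, and an effect of the deletion remain open and untested.

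The 3 matrix lists were called higher in the knockout by camera with the preset correlation but not with an estimated one (adjusted p = 0.856 to 0.907), and their mean score overlapped between the groups (6.54, 6.41 and 6.00 in the wild type, 6.40, 6.97 and 7.14 in the knockout). Transcript length and tubule share could produce such a shift. The union of the 3 matrix lists (82 genes) had a median of 0.57 before and 0.52 (interval 0.42 to 0.58) after removal of the transcript length trend, which argues against length as the whole cause. For oxidative phosphorylation the median went from -0.29 to -0.18 (interval -0.23 to -0.11), so length and other causes cannot be told apart there, because the interval holds the -0.14 that would mark a halved effect. A lower share of tubule cells would raise the markers of the other cells alike, but the 139 markers in 9 lists of endothelium, podocytes, smooth muscle and immune cells had a median of 0.12 (interval 0.03 to 0.19), which the matrix median exceeded by 0.45 (interval 0.32 to 0.61). The difference of the 2 mean scores was 2.44, 2.48 and 2.06 in the wild type and 2.56, 2.75 and 3.15 in the knockout. This argues against a like rise of all other cells as the whole cause, although the same scores against endothelium alone overlapped. The intervals given here resample genes and do not measure the spread between libraries. Mean proximal tubule scores were 7.03, 7.20 and 8.28 in the wild type and 7.96, 7.38 and 6.05 in the knockout. The matrix score was lowest where they were highest and highest where they were lowest, so a part played by tubule share stays open. Against the 139 markers, the matrix median was higher by 0.27 without knockout replicate 3 and by 0.17 with replicate 3 of both groups left out. A change in fibroblasts, whose markers had a median of 0.42, and an effect of the deletion remain open.

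The muscle genes Myh4, Myh1 and Ckm were at or near 0 in the knockout libraries and at a similar low level in all 3 wild-type libraries, and muscle RNA in the latter is a candidate explanation. It predicts a median under -1 for a second list of muscle genes, of which 11 of 15 were measured, and the median was -0.47 (interval -0.58 to 0.01), above the bound set beforehand. That bound was poorly chosen, because 6 of the 11 genes have a knockout level above the 0.627 CPM to be explained, so that adding this amount would not double them. Eno3, Mybpc2 and Pygm lie far above it, at 27.4, 25.4 and 9.71 CPM, whereas Atp2a1, Actn3 and Casq1 lie nearer, at 0.846, 1.22 and 1.45 CPM, and went different ways, at -1.29 ± 0.39, 0.0079 ± 0.31 and -0.21 ± 0.41. The other 5, Mb, Cox6a2, Myoz1, Smpx and Tcap, were at 0.558, 0.240, 0.215, 0.364 and 0.184 CPM in the knockout, so adding this amount would more than double them. They were all below 0, at -0.24, -0.52, -0.52, -0.58 and -1.02 (median -0.52), and only Tcap passed the bound. Their levels are low, and whether muscle would add as much of each gene was not tested. Muscle RNA and a difference in the kidney cells themselves therefore cannot be told apart, and an effect of genotype was not tested.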
